A study of Mus musculus with 12 samples.

How the data were processed

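RNA from 12 samples of Hoxa9-ER mouse bone marrow cells was hybridised to Affymetrix whole-genome mouse arrays, 3 on each of day 0, 3, 4 and 5, and groups were taken from the day in the sample labels. The values are the deposited log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes. RMA corrects background, normalizes quantiles and summarises each probe set by median polish. The version of RMA, the chip definition and whether all arrays were processed together are not given in the sources used here. The values ran from 2.393 to 14.67, which is the range of log2 RMA values, and array medians from 5.952 to 6.024. RMA gives no detection call, so no gene is called absent. Levels of different probe sets are used only to pick or group probe sets by brightness and are not read as amounts of different transcripts. Quantile normalization removes any change that is shared by most transcripts.

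The table held 45101 probe sets, of which 64 were Affymetrix controls. Of the rest, 34945 were paired with 1 gene symbol, 932 with several and 9160 with none in the probe annotation used here, and the latter 2 classes entered no comparison of genes. The Entrez IDs of 34741 probe sets were found in the RefSeq gene table (assembly GRCm38.p6, used for names only), and 0 symbols changed. For each gene the probe set with the highest mean over all arrays was used, which gave 18193 genes, 9010 of them with more than 1 probe set. Among 6092 such genes called on day 5, 312 had another probe set called in the opposite direction. No filter on dim genes was applied.

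Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) in 1 fit of all 12 arrays with a mean per day and no covariate, so that the 4 groups shared an estimate of the spread. The p-values were adjusted by Benjamini-Hochberg over genes, or over lists, within a comparison, and a gene was called at an adjusted p below 0.05. All 6 comparisons between days and a moderated F test over the 4 days were made. Differences are log2 values of the later day minus the earlier day. The 33 gene lists named 870 members, of which 784 were measured here. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and counts adjusted over the list alone are given beside those over all genes. Members of a list are not independent, and some genes belong to more than 1 list.

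Genes named in the text followed a rule written before the data were examined. It took the 10 largest rises and 10 largest falls of day 5 against day 0 among called genes whose 3 values on each day did not overlap, and the 5 largest each way for day 3 against day 0, day 4 against day 0 and day 5 against day 3. It added from each list up to 4 members with the smallest p on day 5 and 2 more in the other direction. Hoxa9, Meis1, Esr1, Itgam, Kit, Cd34, Myb, Mpo, Elane and the Affymetrix controls were always included, and the Gr1 antigen genes are not analysed here. Genes known only by a clone or model number were passed over. Other genes in the closing part were chosen after their values were seen, as stated there, and so were 5 further gene lists on alternative and classical macrophage activation, lipid handling, osteoclasts and the mitochondrial respiratory chain.

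The limma step was tested on simulated data before use. In 20 simulations of day 5 against day 0 over 18193 genes with 200 changed genes, 79.6% of genes changed by log2 0.5 were called, 99.9% at 1 and 100% at 2, and 5.89% of calls were false. RNA quality was checked from the 3' and 5' control probe sets with two-sided exact permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1. By exact permutation, two-sided, Gapdh gave p = 0.4, 0.7 and 0.6 and beta-actin p = 0.6, 1 and 0.1 for day 3, 4 and 5 against day 0. Within day 4 the beta-actin values were uneven, with a log2 ratio of 0.191 for replicate 1 against 0.0156 and 0.0228 for replicate 2 and 3. No batch or scan date is given in the sources used here. Alternatives covered the choice of probe set, the filter on dim genes, the scaling of the arrays, the variance model, array weights, the arrays in the fit, the replicate number as a block, and each array left out in turn. Cyclic loess was added after the data were seen. Leaving out day 4 replicate 1 was planned with the other arrays, and it was singled out after its controls were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.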

Results

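RNA levels were measured in mouse bone marrow cells that carried a retrovirus for Hoxa9-ER, a fusion of the homeobox protein Hoxa9 with a modified hormone-binding domain of the estrogen receptor. Hoxa9 holds myeloid progenitors in an immature, dividing state, and fusions of this kind are active while 4-hydroxytamoxifen is present. The cells grew in medium with interleukin-3, and the design text describes washing and culture with or without 100 nM 4-hydroxytamoxifen. The 12 arrays came from day 0, 3, 4 and 5, with 3 arrays per day. The labels give the day of each array but not whether 4-hydroxytamoxifen was present, so the comparisons below are between days and are not assigned to its addition or removal. Nothing in the labels says that the 3 arrays of a day came from separate cultures, so the p-values measure the spread between these samples, which can be technical. All values are log2 RMA values of 1 probe set per gene, with n = 3 arrays per day, and the number of arrays limits the precision.

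The 2 brightest probe sets for the parts of the fusion stayed high on all days. Both lay near the highest value measured, 14.67, where changes can be understated. A steady level there need not mean an unchanged amount of RNA. The Hoxa9 probe set had a level of 13.37 ± 0.07 (SD, n = 3) on day 0 and 13.65 ± 0.04 on day 5, a rise of 0.28 (limma, adjusted p = 0.00761). The Esr1 probe set, named for the estrogen receptor gene, had 13.88 ± 0.04 on day 0 and 14.05 ± 0.01 on day 5, a rise of 0.17 (adjusted p = 0.0135). A mean over the 3 probe sets of Esr1 turned that difference to -0.58, and without an intensity trend in the variance it was not called (adjusted p = 0.0625). In a fit of every probe set by itself, the second Hoxa9 probe set stood at 3.81 on day 0 and 3.89 on day 5 and was not called (adjusted p = 0.562), whereas the other Esr1 probe sets fell by 0.95 (adjusted p = 3.44e-06) and 0.96 (adjusted p = 2.46e-06). Meis1, a homeobox partner of Hoxa9, fell by 0.72 by day 5.

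Over the time course, 11032 of 18193 genes (60.6%) differed among the 4 days by limma's moderated F test, against a median within-day SD of 0.116 over genes. Across all 45101 probe sets, controls included, arrays of the same day correlated at 0.993 to 0.998, and arrays of day 0 and day 5 at 0.951 to 0.960. Probe sets are not independent replicates. The distance from day 0 grew with time, with 587 genes changed at least 2-fold on day 3, 846 on day 4 and 2205 on day 5. Day 4 replicate 1 stood apart from the other arrays in its controls. Its 18S ribosomal RNA control was at 7.95 against 5.08 to 6.38 on the other arrays, and its root mean square deviation from its day mean was 0.146, the largest of the 12. Its log2 ratio of 3' to 5' beta-actin signal was 0.191, against at most 0.108 on the other arrays. Its BioB and CreX controls were the lowest of the 12 (8.12 and 13.09). The day 5 arrays differed as a group too. Their 18S control was at 6.075 to 6.38, above all arrays of day 0 (5.075 to 5.958) and day 3 (5.507 to 5.745). The upper quartile of their values was 8.134 to 8.201, against 8.297 to 8.403 on day 0. Whether this came from the RNA, the processing or the cells was not tested.

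**Figure D1:**
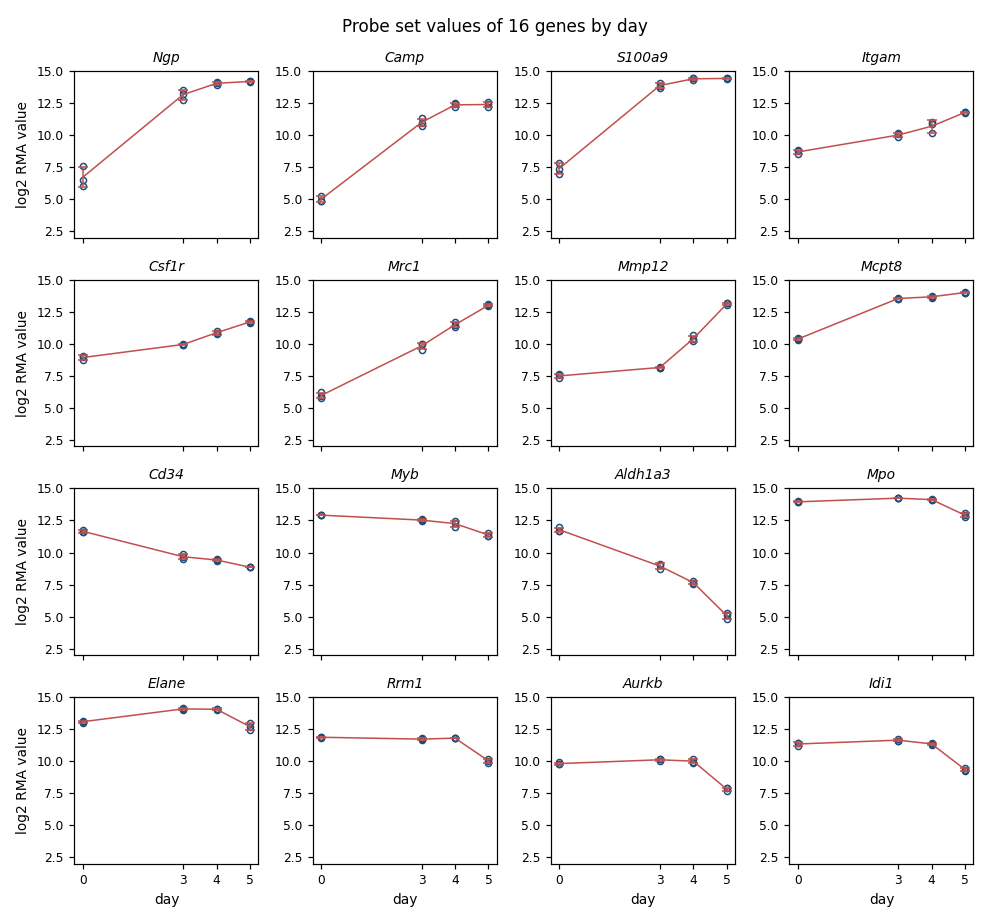
Log2 RMA value (vertical axis) against day (horizontal axis) for 16 genes, where open circles are single arrays, the line joins the day means and bars are SD over 3 arrays. Granule and macrophage genes such as Ngp and Mmp12 climbed from day 0 to day 5, Cd34 and Aldh1a3 declined from day 3 on, and Rrm1, Aurkb and Idi1 were lower on day 5 than on the earlier days.

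Day 5 was set against day 0 to ask how far the cells had moved by the last time point. Genes of mature granulocytes and macrophages rose, and genes of progenitors, of cell division and of ribosome assembly fell. With an estimated correlation the lists of DNA replication (adjusted p = 0.0551), G2 and mitosis (adjusted p = 0.0804) and ribosome biogenesis (adjusted p = 0.0587) lost their calls. The largest rises included Ccl12, a chemokine for monocytes (4.61 ± 0.11 to 12.74 ± 0.14, a rise of 8.14, adjusted p = 1.82e-17). Stfa2l1 of the stefin protease inhibitors rose by 8.12, Ltf, the lactoferrin of specific granules, by 8.04, and Arg1, arginase 1, by 8.00. Olfm4 (7.69), Ngp (7.47), Camp (7.39), Lgmn (7.31), Cdh1 (7.27) and Atp6v0d2 (7.13) completed the 10 largest rises. Several of these started low, Olfm4 at 3.15 and Cdh1 at 3.84 on day 0, and RMA gives no detection call, so such rises can be understated and the order among these genes is not resolved. The largest fall was in Aldh1a3, an enzyme of retinoic acid synthesis, which went from 11.77 ± 0.16 to 5.07 ± 0.24, a difference of -6.70 (adjusted p = 2.88e-17). Gulp1 (-5.16), Rasl11a (-4.56), St8sia6 (-4.51), Btn1a1 (-4.50), Vat1l (-4.30), Pde11a (-4.25), Mylk (-3.94), Crhbp (-3.89) and Bex6 (-3.85) followed. Several falls ended low, Gulp1 at 4.59 and Pde11a at 4.37 on day 5, so such falls can be understated and their order is not resolved either. In all, 5286 genes were higher and 5536 lower on day 5, of which 992 and 1213 changed at least 2-fold. Cyclic loess turned this split to 5531 higher and 4330 lower (56.1% higher, against 48.8%). The 3 values of each day did not overlap for 64.7% of genes, where chance gives 10%.

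The list of secondary and tertiary neutrophil granules rose without exception among its measured members. Not all genes it names are granule proteins or particular to neutrophils. Cebpe is also in the myeloid transcription factor list, Chil3 in the alternative activation list and Mmp9 in the osteoclast list. All 26 rose by day 5 (26 adjusted over the list alone), with a median difference of 4.21 (camera, adjusted p = 9.86e-21, adjusted p = 0.0204 with an estimated correlation). Beside Camp, a cathelicidin, Wfdc21 rose by 5.85, Adam8 by 4.40 and Padi4, which citrullinates histones in neutrophils, by 3.25. S100a9, a calcium-binding protein of neutrophils, went from 7.42 ± 0.42 to 14.43 ± 0.03. Members of the primary granule list did not move together. On day 5, 4 of 13 were higher and 9 lower (13 adjusted over the list alone, median -0.54, adjusted p = 0.0733), and the list was called lower without day 5 replicate 1 (adjusted p = 0.0317), with the replicate number as a block (0.0493) and without genes shared with other lists (median -0.96, adjusted p = 0.0437). Over all alternatives tested with camera its adjusted p ran from 0.0317 to 0.624. Mpo, myeloperoxidase, fell by 1.05 and Elane, neutrophil elastase, by 0.39. Mgst1 rose by 1.06 and Hdc, which makes histamine, by 1.94. Neither of these risers is a primary granule protein, and Hdc is also in the mast cell and basophil list. Plac8 and Ms4a3, which are markers of immature myeloid cells rather than granule enzymes, fell by 0.96 and 1.55.

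Monocyte and macrophage markers rose in 25 of 30 measured genes and fell in 3 (28 adjusted over the list alone, median 2.76, camera adjusted p = 6.06e-14, adjusted p = 0.00586 with an estimated correlation). Mrc1, the mannose receptor, rose by 7.04, Klf4, a transcription factor of monocytes, by 6.10, Mmp12, macrophage elastase, by 5.62 and Lpl, lipoprotein lipase, by 4.40. Irf8 and Ccr2 of the same list fell by 0.77 and 0.45. Itgam, the Mac1 antigen used for flow cytometry in the design text, rose from 8.70 ± 0.15 to 11.78 ± 0.03. Pattern recognition receptors rose in 24 of 27 genes and fell in 2 (26 adjusted over the list alone, median 1.49, adjusted p = 3.08e-10, adjusted p = 0.00586 with an estimated correlation), with Clec4n up by 5.14, Clec4a2 by 4.64 and Clec7a by 4.10, while Irak3 fell by 1.05. Chemokines and inflammatory cytokines rose in 27 of 34 genes and fell in 2 (29 adjusted over the list alone, median 1.60, adjusted p = 1.32e-11, adjusted p = 0.0386 with an estimated correlation). Ccl7 rose by 6.27, Ccl6 by 4.95 and Il6 by 4.05, and Tnfsf9 fell by 2.28. Myeloid cytokine receptors rose in 23 of 28 genes and fell in 3 (26 adjusted over the list alone, median 0.97, adjusted p = 9.46e-08, adjusted p = 0.0489 with an estimated correlation). Csf1r, the receptor for the macrophage growth factor, rose by 2.78 and Ccr1 by 3.68, whereas Flt3 fell by 1.97 and Kit by 0.76.

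Phagocyte oxidase and Fc receptor genes rose in 20 of 20 (20 adjusted over the list alone, median 1.45, camera adjusted p = 6.06e-14, adjusted p = 0.0511 with an estimated correlation). Cybb, the catalytic subunit of the phagocyte oxidase, rose by 4.56 and C3ar1 by 3.76. Lysosomal enzymes rose in 20 of 27 and fell in 3 (24 adjusted over the list alone, median 0.41, adjusted p = 1.95e-05, adjusted p = 0.282 with an estimated correlation), led by the cathepsins Ctsl (3.52), Ctss (3.27) and Ctsb (1.91), while Gusb fell by 0.81. Myeloid transcription factors rose in 13 of 18 and fell in 5 (18 adjusted over the list alone, median 1.41, adjusted p = 2.27e-05, adjusted p = 0.0511 with an estimated correlation). Id2 rose by 5.04, Egr2 by 5.64 and Fos by 4.12, while Cebpa and Gfi1 fell by 0.59 and 0.74. Of the interferon-stimulated genes, 18 of 31 rose and 6 fell (24 adjusted over the list alone, median 0.37, adjusted p = 0.0129, adjusted p = 0.256 with an estimated correlation). Usp18 rose by 2.45 and Ifi204 by 3.39, and Ifi47 and Gbp3 fell by 1.55 and 2.53. Dendritic cell and MHC class II genes were higher in 13 of 22 and lower in 4 (17 adjusted over the list alone, median 0.29, adjusted p = 0.101), with Cd74, the invariant chain, up by 4.82 and Flt3 down.

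Markers of other blood lineages moved in the same samples. Mast cell and basophil markers rose in 19 of 23 genes and fell in 2 (21 adjusted over the list alone, median 1.38, camera adjusted p = 3.43e-09, adjusted p = 0.0511 with an estimated correlation). Tpsb2, a mast cell tryptase, rose by 7.12, Fcer1a, the IgE receptor chain, by 4.44, Cma1, chymase, by 3.71 and Mcpt8, a basophil protease, by 3.63. Eosinophil markers rose in 7 of 11 and fell in 1 (9 adjusted over the list alone, median 1.71, adjusted p = 0.00105, adjusted p = 0.245 with an estimated correlation), with Prg2, the major basic protein, up by 6.21 and Epx, eosinophil peroxidase, by 4.40. Megakaryocyte and platelet markers rose in 14 of 17 and fell in 2 (16 adjusted over the list alone, median 0.52, adjusted p = 0.000151, adjusted p = 0.0511 with an estimated correlation). Ppbp rose by 5.44, Thbs1, which macrophages also make, by 5.30 and Vwf by 5.29, while the platelet receptor genes Gp5 and Gp9 fell by 1.47 and 0.45. Erythroid markers rose in 12 of 20 and fell in 2 (15 adjusted over the list alone, median 0.48, adjusted p = 0.00298, adjusted p = 0.0941 with an estimated correlation), with Rhag up by 3.82 and the transferrin receptor gene Tfrc down by 1.54.

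T cell and NK cell markers were higher in 8 of 20 and lower in 1 (8 adjusted over the list alone, median 0.24, camera adjusted p = 0.0315, adjusted p = 0.297 with an estimated correlation). Without day 0 replicate 2 this list was not called (adjusted p = 0.0533), nor with cyclic loess (adjusted p = 0.181), and over all camera alternatives its adjusted p ran from 0.0116 to 0.297. The members that led this list were Il7r (5.83) and Gzmb (2.31), a granzyme that mast cells also make, while Thy1 fell by 1.48. B cell markers were higher in 6 of 17 and lower in 1 (7 adjusted over the list alone, median 0.23, adjusted p = 0.115), and stromal and endothelial markers were higher in 8 of 21 and lower in 4 (11 adjusted over the list alone, median 0.19, adjusted p = 0.465). In the B cell list Cd22 rose by 0.86 and Cd79b fell by 0.72, and in the stromal list Col1a1 rose by 1.01 and Pdgfrb fell by 2.49. Genes that blood cells do not use, taken as background, were higher in 15 of 37 and lower in 1 (13 adjusted over the list alone, median 0.22, adjusted p = 0.0498, adjusted p = 0.49 with an estimated correlation). Over all camera alternatives its adjusted p ran from 0.0186 to 0.49. It was not called with cyclic loess (adjusted p = 0.376) or without any of 8 arrays. These were day 0 replicate 2 (adjusted p = 0.125) and 3 (0.0667), day 3 replicate 2 (0.0505) and 3 (0.0502), day 4 replicate 1 (0.0548), 2 (0.0526) and 3 (0.0506), and day 5 replicate 3 (0.0981). Its single lower gene, Mbp (-0.21), turned to 0.04 with cyclic loess.

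Stem and progenitor regulators fell in 18 of 29 genes and rose in 6 (24 adjusted over the list alone, median -0.72, camera adjusted p = 0.000302, adjusted p = 0.0252 with an estimated correlation). Cd34, a surface marker of progenitors, fell from 11.66 ± 0.11 to 8.85 ± 0.01, Lmo2 fell by 2.05 and Cdk6 by 1.35. Myb, which sustains progenitor growth, fell by 1.55. Prom1 and Gata2 of the same list rose by 3.20 and 1.44. Hox genes and cofactors were higher in 8 of 24 and lower in 4 (12 adjusted over the list alone, median 0.19, adjusted p = 0.236), with Hoxc6 up by 0.75 and Pbx4 down by 1.10.

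Genes of DNA replication and S phase fell in 31 of 32 and rose in 1 (32 adjusted over the list alone, median -1.27, camera adjusted p = 5.58e-16, adjusted p = 0.0551 with an estimated correlation). Tk1, thymidine kinase, fell by 2.19, Rpa2 by 1.88, Rrm1, the large subunit of ribonucleotide reductase, by 1.84 and Lig1 by 1.63, while E2f2 rose by 1.20. Genes of G2 and mitosis fell in 30 of 32, with none higher (30 adjusted over the list alone, median -1.01, adjusted p = 6.01e-14, adjusted p = 0.0804 with an estimated correlation), and Aurkb, a mitotic kinase, fell by 2.00. p53 targets and cell cycle inhibitors rose in 24 of 29 and fell in 3 (28 adjusted over the list alone, median 0.93, adjusted p = 1.32e-09, adjusted p = 0.0511 with an estimated correlation). The inhibitors Cdkn2b and Cdkn1a rose by 3.42 and 2.12, and Mxd1, which opposes Myc, by 2.48. Ribosome biogenesis genes and Myc targets fell in 33 of 33 (33 adjusted over the list alone, median -0.96, adjusted p = 7.17e-15, adjusted p = 0.0587 with an estimated correlation), with Nolc1 down by 1.55 and Srm by 1.16. Myc itself fell by 0.96. Ribosomal proteins had a median of -0.11 with 13 of 20 lower (13 adjusted over the list alone, adjusted p = 0.0143, adjusted p = 0.325 with an estimated correlation), and this direction turned to 0.03 with cyclic loess, where the call was lost (adjusted p = 0.949). Over the camera alternatives the adjusted p ran from 0.00431 to 0.949. Rpl11 fell by 0.31 and Rplp2 by 0.25.

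Among metabolic and stress genes, cholesterol synthesis genes fell in 18 of 19 and rose in 1 (19 adjusted over the list alone, median -0.54, camera adjusted p = 2.27e-05, adjusted p = 0.245 with an estimated correlation). Insig1 fell by 2.16, Idi1 by 2.00 and Dhcr7 by 1.83. The higher member was Sc5d (0.29), whose mean over probe sets was 0.01. With cyclic loess 11 of the 19 cholesterol genes were called lower and the median was -0.33. Glycolysis and hypoxia genes fell in 17 of 25 and rose in 6 (23 adjusted over the list alone, median -0.40, adjusted p = 0.024, adjusted p = 0.487 with an estimated correlation), with Pfkl down by 1.63 and Ndrg1 up by 1.93. This list was not called with cyclic loess (adjusted p = 0.146) or without day 0 replicate 1 (adjusted p = 0.054), and over all camera alternatives its adjusted p ran from 0.0116 to 0.497. Heat shock proteins fell in 11 of 15 and rose in 2 (13 adjusted over the list alone, median -0.68, adjusted p = 0.00311, adjusted p = 0.0511 with an estimated correlation). Fkbp4 fell by 1.92 and Hspa8 by 0.68, while Hmox1, heme oxygenase, rose by 2.48. Apoptosis regulators rose in 10 of 22 and fell in 3 (14 adjusted over the list alone, median 0.23, adjusted p = 0.027, adjusted p = 0.235 with an estimated correlation), with the death-promoting Fas (1.94) and Bcl2l11 (1.82) and the survival genes Mcl1 (0.75) and Bcl2l1 (0.99) all higher. JAK-STAT feedback genes rose in 11 of 18 and fell in 6 (17 adjusted over the list alone, median 0.53, adjusted p = 0.0304, adjusted p = 0.365 with an estimated correlation), with Osm up by 2.49 and Socs2 down by 1.91. The apoptosis and JAK-STAT lists were not called once genes shared with other lists were left out (adjusted p = 0.101 and 0.253), and over all camera alternatives their adjusted p ran from 0.00141 to 0.235 and from 0.00943 to 0.365. Amino acid and ER stress genes went both ways, 14 of 29 higher and 12 lower (26 adjusted over the list alone, median 0.11, adjusted p = 0.244), with Trib3 up by 2.84 and Psat1 down by 0.91. Cyclic loess called this list higher (median 0.36, adjusted p = 0.0401), and over all camera alternatives its adjusted p ran from 0.0288 to 0.49. Estrogen-responsive genes were higher in 8 of 15 and lower in 3 (13 adjusted over the list alone, median 0.33, adjusted p = 0.06), led by Ltf, which is also a granule gene, while Igfbp4 fell by 1.30. Without day 0 replicate 1 (adjusted p = 0.0497) or 2 (adjusted p = 0.0451) the estrogen list was called higher, and over all camera alternatives its adjusted p ran from 0.0451 to 0.187.

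For day 5 against day 0, 26 of 33 lists were called, 18 higher and 8 lower, and 6 of these calls held with an estimated correlation, those of the granule, monocyte, pattern receptor, chemokine, cytokine receptor and progenitor lists. The ratio of 3' to 5' signal for the beta-actin control was lower on day 5 than on day 0 (log2 0.03 against 0.09; exact permutation p = 0.1, the smallest that 3 against 3 arrays can give), and day and any processing batch cannot be told apart.

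**Figure D2:**
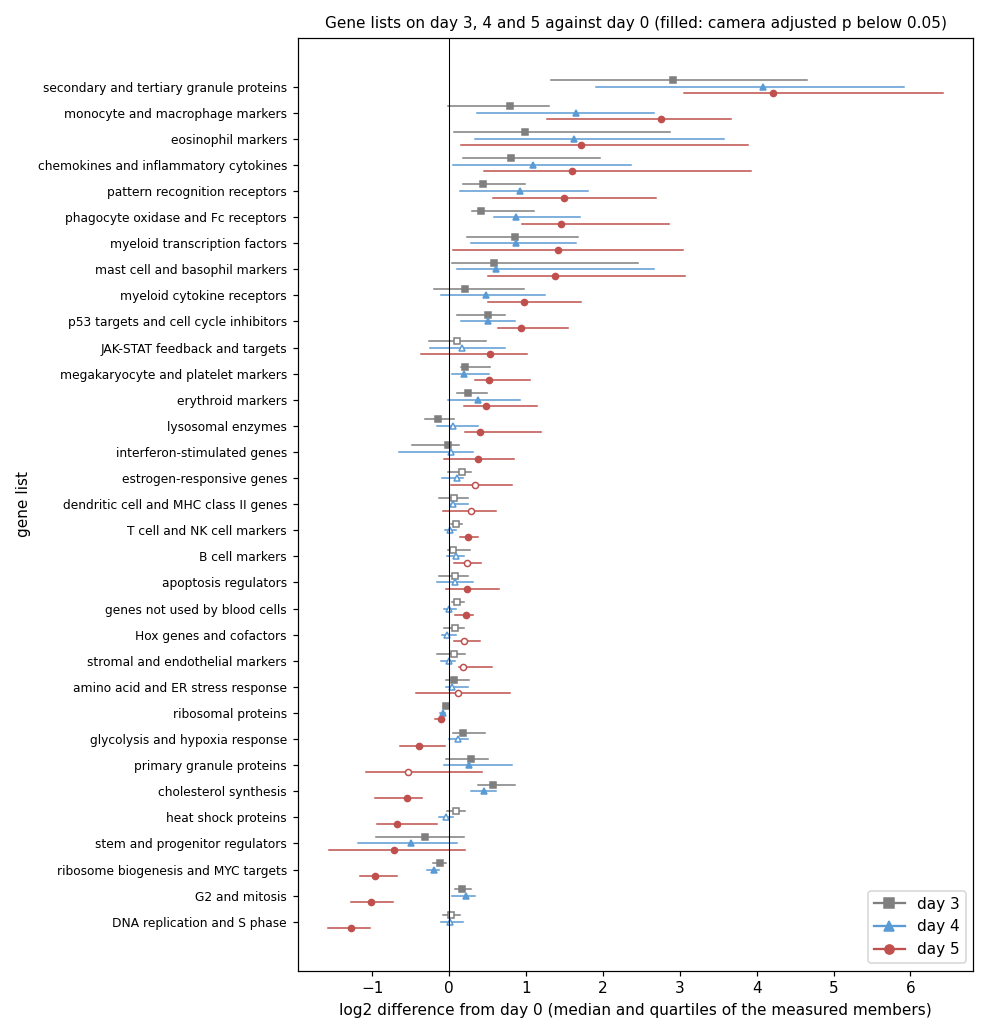
Median log2 difference from day 0 (horizontal axis) of the measured members of 33 gene lists (vertical axis) on day 3, 4 and 5, with lines over the quartiles of the members and filled symbols for a camera adjusted p below 0.05. The secondary and tertiary granule list had medians of 2.91, 4.08 and 4.21, and the cholesterol synthesis list changed side, with medians of 0.57, 0.45 and -0.54.

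Day 3 was set against day 0 to show the earliest change sampled. The largest rises included S100a9, Ngp and Camp of the secondary and tertiary granule list. S100a9 went from 7.42 ± 0.42 to 13.88, a rise of 6.46 (adjusted p = 1.25e-15), and Ngp (6.45), Arg1 (6.29), Camp (5.99) and Stfa2l1 (5.76) followed. Camp started low, at 4.86 to 5.26 on day 0, and S100a9 ended near the highest value of 14.67. These rises can be understated too, and their order is not resolved. Crhbp fell by 4.25, Btn1a1 by 4.21, Rasl11a by 3.76, Ddx4, a germ cell helicase, by 3.51 and Khdc1a by 3.39. Of these falls Ddx4 ended at 4.71 and Khdc1a at 4.79, and Btn1a1 ended low as well. Their sizes can be understated, and the order of these falls is not resolved. In the secondary and tertiary granule list 24 of 26 genes were already higher (25 adjusted over the list alone, median 2.91, camera adjusted p = 5.96e-33, adjusted p = 0.014 with an estimated correlation). Primary granule proteins rose in 8 of 13 and fell in 2 (10 adjusted over the list alone, median 0.29, adjusted p = 0.00105, adjusted p = 0.145 with an estimated correlation), with Elane up by 1.00 and Mpo by 0.29. Monocyte and macrophage markers rose in 17 of 30 and fell in 6 (23 adjusted over the list alone, median 0.79, adjusted p = 4.6e-06, adjusted p = 0.0328 with an estimated correlation).

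On day 3 the genes of cell division had not fallen. The DNA replication list had 6 members higher and 4 lower of 32 (11 adjusted over the list alone, median 0.02, adjusted p = 0.706), and the G2 and mitosis list had 15 higher and none lower (16 adjusted over the list alone, median 0.17, adjusted p = 0.000477, adjusted p = 0.402 with an estimated correlation). Aurkb rose by 0.30 and Bub1 by 0.35. Cholesterol synthesis genes rose in 16 of 19 with none lower (17 adjusted over the list alone, median 0.57, adjusted p = 2.61e-09, adjusted p = 0.145 with an estimated correlation), and Scd1, a fatty acid desaturase, rose by 1.95. Stem and progenitor regulators fell in 17 of 29 and rose in 5 (22 adjusted over the list alone, median -0.32, adjusted p = 3.49e-05, adjusted p = 0.0143 with an estimated correlation), with Cd34 down by 1.98 and Lmo2 by 1.45. Across all genes 2262 were higher and 2678 lower on day 3 (45.8% higher), and cyclic loess turned this to 2919 higher and 2052 lower (58.7%). On day 3, 22 of 33 lists were called, and 6 of those calls held with an estimated correlation.

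On day 4 the 5 genes with the largest rises on day 3 again had the largest rises, Camp (7.36), Ngp (7.33), Stfa2l1 (7.32), Arg1 (7.24) and S100a9 (6.98). Camp started low, at 4.86 to 5.26 on day 0, and S100a9 ended at 14.335 to 14.452, near the highest value of 14.67. Such rises can be understated, and the order among these genes is not resolved. Large falls against day 0 were seen in Btn1a1 (-4.62), Rasl11a (-4.44), Pde11a (-4.38), Crhbp (-4.34) and Gulp1 (-4.14). Btn1a1 ended at 4.44 and Pde11a at 4.23, so their falls can be understated and the order of the 5 is not resolved. All 26 genes of the secondary and tertiary granule list were higher (26 adjusted over the list alone, median 4.08, camera adjusted p = 8.47e-39, adjusted p = 0.00269 with an estimated correlation). Monocyte and macrophage markers rose in 23 of 30 and fell in 4 (28 adjusted over the list alone, median 1.65, camera adjusted p = 7.63e-16, adjusted p = 0.00269 with an estimated correlation). Ribosome biogenesis genes were lower in 21 of 33 (25 adjusted over the list alone, median -0.20, adjusted p = 7.09e-06, adjusted p = 0.308 with an estimated correlation). In all 2457 genes were higher and 3153 lower on day 4 than on day 0, which cyclic loess turned to 2998 and 2630, and 18 of 33 lists were called, of which 8 held with an estimated correlation. Between day 3 and day 4, 908 genes were higher and 344 lower on day 4 (72.5% higher, or 60.8% after a further quantile normalization), and 126 and 4 of these changed at least 2-fold. Lgmn went from 6.50 on day 3 to 9.49 on day 4, and Mmp12 from 8.16 to 10.41. This count of 1252 genes was 1913 without day 4 replicate 1, the array that stood apart, and 814 and 832 without day 4 replicate 2 and 3. It was 803 and 757 without day 3 replicate 1 and 3, and 4334 with array weights. On day 4 the interferon-stimulated genes had a median of 0.02 but a mean of -0.14, and the heat shock proteins a median of -0.04 but a mean of 0.06. Camera gave both a lower direction without a call. Stromal markers on day 3 had a median of 0.07 and a mean of -0.04, also with a lower direction and no call.

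Day 5 was set against day 3 to separate late from early change. Bex1 rose by 7.17 (3.63 to 10.80, adjusted p = 3.45e-12) and Rbp4, a retinol carrier, by 6.63, and neither was called on day 3 against day 0 (adjusted p = 0.404 and 0.646). Both started low on day 3, Bex1 at 3.63 and Rbp4 at 4.53, so their rises can be understated too and their rank is not resolved. The chemokine gene Ccl8 (5.83), the stefin gene Stfa3 (5.56) and Lgmn (5.49) completed the 5 largest rises. The largest falls were in Aldh1a3 (-3.87), Scd1 (-3.16), Bex6 (-2.92), Fads2, another fatty acid desaturase (-2.75), and Mylk (-2.46). Monocyte and macrophage markers rose in 26 of 30 with none lower (27 adjusted over the list alone, median 1.77, camera adjusted p = 6.45e-20, adjusted p = 0.00307 with an estimated correlation), and lysosomal enzymes rose in 24 of 27 and fell in 2 (26 adjusted over the list alone, median 0.54, adjusted p = 4.14e-12, adjusted p = 0.0912 with an estimated correlation). Cell division genes fell in this interval. The DNA replication list had 31 of 32 lower (32 adjusted over the list alone, median -1.28, adjusted p = 8.4e-22, adjusted p = 0.0489 with an estimated correlation), the G2 and mitosis list 31 of 32 (31 adjusted over the list alone, median -1.19, adjusted p = 4.97e-21, adjusted p = 0.0489 with an estimated correlation). Cholesterol synthesis genes fell in 19 of 19 (19 adjusted over the list alone, median -1.30, adjusted p = 3.29e-13, adjusted p = 0.064 with an estimated correlation). Primary granule proteins fell in 9 of 13 and rose in 3 (12 adjusted over the list alone, median -0.92, adjusted p = 0.000273, adjusted p = 0.0737 with an estimated correlation), with Elane down by 1.39 and Mpo by 1.34. Of all genes 3230 were higher and 4583 lower (41.3% higher), and cyclic loess turned this to 4062 and 3755 (52.0%). For this interval 25 of 33 lists were called, and 10 held with an estimated correlation. Between day 4 and day 5, 4473 genes were higher and 4612 lower, which cyclic loess turned to 4711 and 3608, and 415 and 605 of these changed at least 2-fold.

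Across the 3 comparisons with day 0, 1343 genes were higher and 1916 lower on day 3, 4 and 5 alike, 3259 in all. Independent lists of these sizes would share 230. Simulated groups without change, set against the same day 0 arrays, shared 0 calls. They were drawn around the means of those arrays, which leaves out the sampling error of day 0. That 0 was therefore all but fixed in advance and is no yardstick for the 3259. The day 0 arrays are too few to split, so the part of the excess that comes from the shared controls could not be measured. Cd34, Lmo2 and Myb were among the genes lower on each of these days, and Camp, Mrc1 and Mcpt8 among those higher. A further 239 genes were higher on day 3 and lower on day 5 than on day 0, and 185 were lower on day 3 and higher on day 5. They included Elane, Mpo, Gfi1 and Scd1 in the first direction and Ctsd, the gene of cathepsin D, in the second.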

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

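The tests on cholesterol synthesis and on the fusion were chosen after their results had been seen, and the tests on background genes and lymphoid markers and the counts over other splits before. Groups of 3 arrays are too small for a test of single outlying values.

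Cholesterol synthesis genes differed between time points, higher on day 3 (median 0.57) and lower on day 5 (-0.54) than on day 0, with a median of -1.30 for day 5 against day 3 (adjusted p = 3.29e-13, camera in limma, adjusted p = 0.064 with an estimated correlation, and 0.145 and 0.245 for day 3 and day 5 against day 0). After cyclic loess that median was still -1.13, which argues against an intensity-dependent shift of the arrays as its whole cause. A single aberrant array is argued against too, because the median reached at most -1.28 with any array of these days left out. For day 5 against day 0, cyclic loess left 11 members called lower (18 before) and a median of -0.33. A part played by the shift stays open there. Cell division as the whole source of the rise on day 3 is argued against by the DNA replication list, whose median on day 3 was 0.0241 (95% bootstrap interval -0.0424 to 0.103) against 0.572 for the cholesterol genes. The G2 and mitosis list was higher on day 3, though by less (15 of 32, median 0.168, adjusted p = 0.000477, adjusted p = 0.402 with an estimated correlation), so a part played by cell division stays open. A difference in medium, handling or processing between days stays open, since each day is its own group, and a response of the cells to the culture time may also contribute; neither was tested.

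Genes that blood cells do not use were slightly higher on day 5 (15 of 37 called higher), as were some markers of B cells, T cells and stroma. The call of the background list (camera, adjusted p = 0.0498) was lost with an estimated correlation (0.49). It was also lost with the mean of a gene's probe sets (0.069), arrays centred on their median (0.0528) or shared genes left out (0.0518). Pooled, the markers of B cells, T cells and stroma exceeded the background genes by only 0.00565 in median (95% bootstrap interval -0.08 to 0.155). This argues against RNA from lymphoid and stromal cells as a source that raised most of these markers. A pooled median cannot exclude RNA of a single lineage or RNA seen in a few markers. The T cell and NK cell list alone was called higher (camera, adjusted p = 0.0315, 0.297 with an estimated correlation). An intensity-dependent shift may account for part of the rise: the median difference of all genes was 0.129 and 0.23 in the lower 2 of 4 groups of genes ranked by level and -0.231 and -0.216 in the upper 2. After cyclic loess 10 background genes were still called higher and the list's median fell from 0.22 to 0.12, which ended its call (adjusted p = 0.0498 before and 0.376 after), so the share due to the shift cannot be told apart from a change in the cells.

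The Esr1 and Hoxa9 probe sets that stayed bright may both read the fusion transcript, while the other Esr1 probe sets, which fell by 0.95 and 0.96, may read the cells' own Esr1 transcript. The within-day deviations of the bright pair correlated at 0.99, above 99.7% of the correlations with 294 equally bright probe sets. With the deviations of day 4 replicate 1 dropped the correlation was 0.975, again the 99.7th percentile. The day 4 mean still included that array, so its offset stayed in the other day 4 deviations. Both probe sets varied most on day 4 (SD 0.146 for Esr1 and 0.245 for Hoxa9). The part of the correlation that rests on that array was therefore not measured. A shared brightness artefact of those probe sets stays open, since probe positions were not analysed here.

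Other results were on opposite sides of day 0 on day 3 and day 5, with the difference between day 5 and day 3 passing limma's test, which for a single gene follows from its calls on both sides. The G2 and mitosis list had a median of -1.19 for day 5 against day 3, the interferon-stimulated genes 0.49, the lysosomal enzymes 0.54 and the glycolysis and hypoxia genes -0.53. With an estimated correlation the G2 list kept this call (adjusted p = 0.0489) and the others lost it (adjusted p = 0.064, 0.0912 and 0.222), and none of these lists kept its call against day 0 on day 3 or day 5. On day 3 the interferon-stimulated genes lay close to day 0 in median (-0.02, mean -0.25), with 4 of 31 higher and 12 lower. The glycolysis list lost its call on day 5 with cyclic loess (adjusted p = 0.146, in a range of 0.0116 to 0.497 over all camera alternatives). Genes that fell from day 3 to day 5 were Aurkb (-2.30), Bub1 (-1.77), Dhcr7 (-2.21), Elane (-1.39), Gfi1 (-1.46), Idi1 (-2.30), Mpo (-1.34), Scd1 (-3.16), Stard4 (-1.47) and Siglecf (-0.59). Genes that rose were Blnk (2.26), Cd28 (1.40) and Ctsd (1.05). The fall of Siglecf below day 0 was not called with cyclic loess (-0.03) or a further quantile normalization (-0.09), nor without day 0 replicate 2 (-0.21) or 3 (-0.21). Among the 10092 probe sets without a single gene, which entered no comparison, 221 were at least 2-fold higher and 360 at least 2-fold lower on day 5 than on day 0.

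Other splits of the arrays bear on each count. Of 100 splits of the 12 arrays into 4 groups of 3, only 1, the real split, gave as many genes that differed among the days (11032, highest other 2218). Only 1 gave as many calls shared by day 3, 4 and 5 (3259, highest other 0). For both counts this share is under 0.05, and it is the smallest that 100 splits can give. Splits that mix days count the differences between days as spread, so they tend to give few calls. They cannot speak to a culture or batch shared by the arrays of a day. For each pair of days, 6 arrays make 10 splits, too few for a share under 0.05. Counts of called genes were 4940, 5610, 10822, 1252, 9085 and 7813 for day 3, 4 and 5 against day 0, day 4 against day 3, day 5 against day 4 and day 5 against day 3, with 1 split as high (the real one) and 0 as the highest other in each. Counts with at least 2-fold change were 587, 846, 2205, 130, 1020 and 1378, also with 1 split as high and 0 as the highest other. Counts of called lists were 22 for day 3, 18 for day 4 and 26 for day 5 against day 0 and 25 for day 5 against day 3. As many lists were called in 1, 4, 1 and 2 of the 10 splits, with highest other counts of 15, 20, 23 and 26. Splits that mixed days thus called many lists at the preset correlation, although they called 0 genes. Mixed splits still keep part of the difference between days. The number of lists called at that setting is therefore weak evidence that the real days differ.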

How the results depend on the processing

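Cyclic loess was chosen after the data were seen, and the other settings were planned, among them each array left out, of which day 4 replicate 1 was singled out after its controls were seen. Counts of calls stayed within 1.5 times the count reported under all settings run but those named next. Keeping 7686 genes above the dim filter level gave 6907 genes that differed among the days (reported 11032), 6379 for day 5 against day 0 (10822) and 5711 for day 5 against day 4 (9085). These counts were lower because fewer genes were tested. As shares of the 7686 genes they were larger than the reported counts are of 18193 genes. The filter level, 8.06, was set by background genes that were bright here, such as Mbp. Array weights gave 4334 for day 4 against day 3 (1252), and leaving out 1 array gave 757 (without day 3 replicate 3) to 1913 (without day 4 replicate 1). Without day 3 replicate 1 it was 803, and without day 4 replicate 2 and 3 it was 814 and 832; the cause was not tested. With an estimated correlation 6, 8, 6 and 10 lists were called (reported 22, 18, 26 and 25). Of 132 list results 61 lost their call in this way, 5 with cyclic loess, which gave 2 more a call, and 3 without shared genes, which gave 2 more a call. Of 112 above the dim filter level 13 lost it and 1 gained it. Fry gave 19 more lists a call, but it does not compare a list with other genes. At 2-fold, 484 genes were shared by the 3 days (3259), as fewer genes pass. Reversed were Esr1 with the mean of its probe sets (-0.58, reported 0.17), where its probe sets disagree, Mbp without _s_at and _x_at probe sets (0.0248) and with cyclic loess (0.0418, reported -0.21), and ribosomal proteins with cyclic loess on day 5 against day 0 (0.0288, reported -0.11), where the call was lost (adjusted p = 0.949), and against day 3 (0.112, reported -0.06), where a call as higher was gained (adjusted p = 0.0171, reported 0.122); the cause was not tested. No scaling moved the median of all genes by over 0.1. The replicate numbers did not pair the arrays throughout, although number 2 did so in 6 of 6 pairs of days at a correlation over 0.1. The correlations of same-numbered deviations ran from -0.0458 to 0.114, 0.119 to 0.231 and -0.0782 to 0.0313 for numbers 1, 2 and 3, and 6 of 12 arrays correlated best with their own number. With the replicate number as a block 5224, 5756, 11062, 1454, 9369 and 7990 genes were called for day 3, 4 and 5 against day 0, day 4 against day 3, day 5 against day 4 and day 5 against day 3, and 22, 18, 27 and 25 lists. Of 17 counts and 132 list results 1 list, primary granule proteins, changed its call. Low signal limits what RMA values of dim probe sets can show, and levels near the top of the range limit what bright ones can show.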

Other observations

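The 5 gene lists in this part were chosen after the data had been seen, and so were the tests on alternative activation. Genes named here that the naming rule did not select were chosen after their values were seen. The lipid handling genes of macrophages rose on day 5 in 17 of 22 measured genes and fell in 3 (median 1.78, camera in limma, adjusted p = 2.41e-07, adjusted p = 0.0297 with an estimated correlation). Fabp4, a fatty acid carrier, rose by 6.43, Cd36, a scavenger receptor, by 5.02, Mertk, a receptor for dying cells, by 4.33 and Pparg, a lipid-sensing nuclear receptor, by 4.05, while Scarb1 fell by 1.00 and Angptl4 by 0.85. Of 17 osteoclast genes 12 were higher and 2 lower on day 5 (median 0.54, adjusted p = 0.000887, adjusted p = 0.122 with an estimated correlation), led by Atp6v0d2 (7.13), Mmp9 (3.85) and Ctsk (3.68), while Acp5 had a difference of 0.21 (adjusted p = 0.185). All 25 measured genes of the mitochondrial respiratory chain were lower on day 5 (median -0.41, adjusted p = 3.54e-08, adjusted p = 0.129 with an estimated correlation), with Ndufa4 down by 1.35; after cyclic loess 15 were called lower and the median was -0.25.

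Alternative macrophage activation, the program that interleukin-4 and interleukin-13 induce, was looked at because several of its genes were among the largest rises. Of 26 measured list genes 25 were higher and 1, Socs2, lower on day 5 (median 3.22, adjusted p = 1.33e-14, adjusted p = 0.0504 with an estimated correlation). They were higher before that, in 17 genes on day 3 (median 1.09, adjusted p = 8.7e-13, adjusted p = 0.0949 with an estimated correlation) and in 24 on day 4 (median 1.79, adjusted p = 5.4e-21, adjusted p = 0.0279 with an estimated correlation). Classical activation genes were higher in 11 of 22 and lower in 1 (median 0.29, adjusted p = 0.000958, adjusted p = 0.0594 with an estimated correlation). Fpr2 rose by 4.11, Il6 by 4.05, Il1b by 3.99, Saa3 by 3.19 and Socs3 by 2.66, and Il12a fell by 1.36. The mean over the list was 1.01. Nos2, the inducible nitric oxide synthase, had a difference of 0.09 (limma, adjusted p = 0.544). Nos2, Il12b and Cxcl9 stood low on day 5 (5.49, 4.01 and 4.69), where changes can be missed.

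A hypothesis is that part of the change by day 5 may be a wider alternative activation response. To test it on genes not used to form it, members named by the rule, held in the first lists or seen beforehand among large changes were left out, which kept 10 genes. A first run had kept Retnla, Ccl24 and Mgl2, seen beforehand, and gave 13 genes with a median of 2.66 and 2.37 above the classical genes; they were then removed. All 10 remaining genes were higher, with a median of 1.72 (camera, p = 3.4e-07; p = 0.0134 with an estimated correlation), among them Fn1 (4.99), Rnase2a (3.84) and Tgm2 (3.05). Their median exceeded that of the classical genes by 1.43 (one-sided permutation test, p = 0.0329, 95% bootstrap interval 0.633 to 2.86). Fpr2, Il6, Il1b, Saa3 and Socs3 of the classical set each rose by more than 1.72. The difference in medians therefore does not mean that classical genes stayed flat. Monocyte and macrophage markers (median 2.76) and eosinophil markers (1.71) were higher on day 5 too. With an estimated correlation the monocyte list kept its call (camera, adjusted p = 0.00586) and the eosinophil list lost it (0.245). A larger share of such cells would also raise these genes and stays open beside activation. Genes are not independent replicates, so these p-values describe these genes and arrays only. The permutation test and the bootstrap shuffled or resampled genes, so they do not measure the spread between arrays. Genes seen beforehand were left out of the alternative set only. The classical set kept all 22 genes, of which 7 had not been seen.

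Transcription of Il4 or Il13 in the culture was tested as a candidate source of such a signal. Il4 rose by 3.37 on day 5 (5.66 to 9.03) and Il13 by 1.98 (6.53 to 8.51), and both were already higher on day 3, by 3.60 and 2.36. Both genes belong to the mast cell and basophil list, of which most members were already known to rise, so the test was not blind. Whether the transcripts were translated, and which cells held them, was not analysed here.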
